A study of Mus musculus with 20 samples.

How the data were processed

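The data are read counts from kidneys of 20 male mice, with 1 library per mouse, in 4 groups of 5. The groups cross genotype, Tert+/+ or Tert-/- of generation 3 (G3), with an age of 7 or 47 weeks, called young and old here. Groups were taken from the genotype and age of each library in the labels. Replicates were numbered in the order in which the libraries are listed, so equal numbers do not pair mice, and the labels give no litter, day or batch. Libraries were made with a kit that reads the 3′ end of polyadenylated RNA on the sense strand (QuantSeq), from 300 ng of RNA with a mean quality score of 6.6 (range 5.0 to 7.5), per the labels' protocols. RNA quality per library is not given in the sources used here.

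The deposited signal in each library is a normalized read count, which the authors made by dividing the reads of each gene by 1 size factor per library. That reading rests on the table's name and on its values. In every library, 100% of the values were whole multiples of 1 step (relative tolerance 1e-06), with steps from 0.8304 to 1.1261, so whole reads could be recovered by division. The build is GRCm38, and FastQC 0.11.7, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19, HTSeq 0.6.1 and DESeq2 are named without roles in the submitters' processing notes. The table holds 19940 genes, each above 0 in at least 6 libraries and with at least 11 reads over all libraries. Recovered totals were 7161690 to 9757594 reads per library, and 18628 to 19137 genes were above 0. A value of 0 allows up to 3 reads, or 2.49 to 3.38 normalized counts depending on the library, which covers counting error only. Differences between mice were larger than counting error: over the 40 pairs of replicates within groups, chi-square per degree of freedom was 3.59 to 86.57 among genes with at least 10 reads.

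Genes were kept when their normalized count was 10 or more in at least 5 libraries, which left 14630. The values were transformed to log2(normalized count + 1) and fitted with limma 3.58.1 in R 4.3.3, with a trend of the spread on intensity and 1 model of 4 group means over all 20 libraries. Contrasts were G3 Tert-/- against Tert+/+ at each age, old against young in each genotype, and the interaction, which is the genotype effect at 47 weeks minus that at 7 weeks. Each test was two-sided with Benjamini-Hochberg adjustment over all tested genes within the comparison, and an adjusted p under 0.05 passed. Unless another source is named, every adjusted p of a gene is from limma. The design, the alternatives and the gene lists were fixed before the data were examined. Correlations of log2 fold changes are across genes, which are not independent replicates, so they carry no p.

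40 gene lists for pathways, nephron segments, other cell types, sex-biased expression and RNA quality were fixed, with 784 entries, of which 738 were in the table and 46 were not. The 36 lists with at least 5 tested members were tested with camera, with a preset correlation of 0.01 between genes and adjustment over lists. The same test with an estimated correlation and the fry test stand beside it. Where only the call by camera is stated, the preset correlation is meant. The lists for neutrophils, adrenal cortex, skeletal muscle and pancreatic acinar cells had too few tested members. A list score per library is the median over members of log2 values, centred per gene over all libraries.

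Genes are named by a rule. For each comparison it takes up to 8 genes with the largest rise and 8 with the largest fall among those that passed, had a mean of at least 20 in the higher group and did not overlap between the groups, apart from genes known only by a Gm number, a Rik name or an identifier. It adds up to 4 passing members of each list, and in the genotype comparisons a panel of injury, fibrosis and epithelial-to-mesenchymal transition genes. Where no gene passes, it takes the 5 with the smallest p. Genes outside the rule are marked in the text as chosen after their values were seen. Cdkn2a, a member of the panel, was not analysed here, and the values of a few genes that the rule takes are not reported here. Coordinates are from GENCODE release M21 on GRCm38, in which 19796 genes (99.3%) matched 1 annotated gene. Reads of close copies could be split or lost in counting, so the values of Cyp4a12a and Cyp4a12b, the immunoglobulin genes, Gm6300 and Gm47283 are uncertain.

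The fit was tested on simulated data for the genotype effect at 47 weeks, with 14630 genes, of which 67 changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. The changed genes were drawn only from those with a mean of at least 20 over all libraries. The fit recovered 31.3% of the genes changed 1.5-fold, 85.1% of those changed 2-fold and 98.5% of those changed 4-fold. With many changed genes an adjusted p under 0.05 is easier to reach than with the 14 real calls. These shares may therefore overstate recovery in the real comparison. 8 of the 151 simulated calls were false (5.3%), and the fit made 1 call in the unchanged comparison at 7 weeks. A simulated 1.5-fold fall of the male-biased list gave an adjusted p of 1.24e-06 with an estimated correlation. No other list passed with the preset correlation. Simulated genes were drawn independently of each other, so this could not show how often lists of correlated genes pass without a real difference.

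Alternatives were other pseudocounts (0.5 and 5), no filter or a filter of 50, TMM factors, quantile normalization, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, a model of only the 10 libraries compared, array quality weights, a robust prior, a fold change of at least 1.5, and leaving out each library in turn. A fit without both libraries that stood apart from the rest was added after the data were seen. Scripts also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.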

Results

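RNA from whole kidneys of 20 male mice was profiled by 3′ RNA sequencing, with 5 mice in each of 4 groups: Tert+/+ and G3 Tert-/- mice at 7 weeks and at 47 weeks. Tert encodes the reverse transcriptase of telomerase, and mice bred for several generations without it have short telomeres. The series title concerns short telomeres, epithelial-to-mesenchymal transition programmes and kidney fibrosis, and the design asks what changes with genotype at each age and with age in each genotype. Libraries held 7161690 to 9757594 reads assigned to genes. Values are normalized read counts, given as mean ± SD over 5 mice, and log2 fold changes are given with their standard errors (SE).

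Tert itself (chromosome 13, 73626911 to 73649843) was counted at low levels in every library. At 7 weeks it was 15.8, 7.72, 10.8, 10.2 and 4.21 in Tert+/+ kidneys and 1.82, 0.979, 5.65, 4.98 and 2.14 in G3 Tert-/- kidneys. At 47 weeks it was 7.25, 7.88, 11.7, 16.9 and 15.6 in Tert+/+ kidneys and 5.28, 8.19, 8.31, 5.11 and 8.08 in G3 Tert-/- kidneys. Group means were lower in G3 Tert-/- mice at both ages, with an exact two-sided permutation p of 0.0238 at 7 weeks and 0.0794 at 47 weeks (the smallest possible is 0.00794). Transcript remained in G3 Tert-/- kidneys, and a 3′ tag can lie outside the deleted part of the gene, so these values check the genotype labels little.

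2 Tert+/+ libraries, young replicate 1 and old replicate 4, stood apart from the other 18. Their scores on the first principal component, which held 22% of the variance, were 67.5 and 56.6, against -39.4 to 21 in the others. The SD over 3985 abundant genes of their departures from the median library was 0.595 and 0.470 log2 units, against 0.161 to 0.384. Both were kept, and their values are given beside the gene groups they move with.

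The genotype comparison at 47 weeks asks what differs with Tert genotype in older kidneys. Telomere length was not analysed here. Old G3 Tert-/- kidneys held less of several tubule transcripts that male mice express more strongly. Slco1a1, an androgen-dependent organic anion transporter of the proximal tubule (chromosome 6, 141907282 to 141946962), fell from 1256 ± 244 in old Tert+/+ to 304 ± 118 in old G3 Tert-/- kidneys (n = 5 each). This is 4.28-fold lower, with a log2 fold change of -2.10 (SE 0.23, adjusted p = 5.73e-05). Acsm3, a medium-chain acyl-CoA synthetase (chromosome 7, 119760923 to 119787513), fell from 897 ± 118 to 431 ± 160, 2.17-fold lower (log2 fold change -1.12, SE 0.19, adjusted p = 0.0145). Scd2, a fatty acid desaturase (chromosome 19, 44293674 to 44306864), rose 2.06-fold, from 105 ± 15.1 to 217 ± 36.4 (log2 fold change 1.04, SE 0.18, adjusted p = 0.0172).

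All 12 tested members of the androgen-responsive and male-biased list had lower values in old G3 Tert-/- than in old Tert+/+ kidneys, with a median log2 fold change of -0.48. The list passed (adjusted p = 4.14e-14, and adjusted p = 0.000421 with an estimated correlation). Slco1a1 and Acsm3 were the 2 members that fell over all genes tested, and 6 fell when adjusted over the list alone. Among those 6 were Cyp4a12a, a fatty acid hydroxylase (log2 fold change -1.86, SE 0.42), the polyamine enzyme Odc1 (-0.76, SE 0.21) and the lysosomal enzyme Gusb (-0.59, SE 0.14). The Cyp4a12a count was 3180 in Tert+/+ old replicate 4, against at most 2083 in the other 19 libraries, and that library also held more of most listed hepatocyte transcripts than any other (Alb 462 against at most 89.8, Apoa1 260.1 against at most 25.4), though not of Apoc3 (105 against up to 115). The female-biased list moved the other way, with all 6 members higher and a median of 1.14 (adjusted p = 6.51e-08, and adjusted p = 0.00986 with an estimated correlation). None of its members passed over all genes, and 5 rose when adjusted over the list alone. Slc7a12, an amino acid transporter that female mice express more highly, was 47.3 ± 25.5 in old Tert+/+ and 152 ± 34.8 in old G3 Tert-/- kidneys (log2 fold change 1.80, SE 0.38, adjusted p = 0.0729). Prlr, the prolactin receptor, was 342 ± 87.3 and 649 ± 164 (log2 fold change 0.91, SE 0.28, adjusted p = 0.436). The female-biased score of Tert+/+ old replicate 4 was -0.94, against 0.22 to 0.33 in the other 4 of its group, and the lists kept their calls without both libraries that stood apart, with an estimated correlation (adjusted p = 0.00117 and 0.00875).

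**Figure D1:**
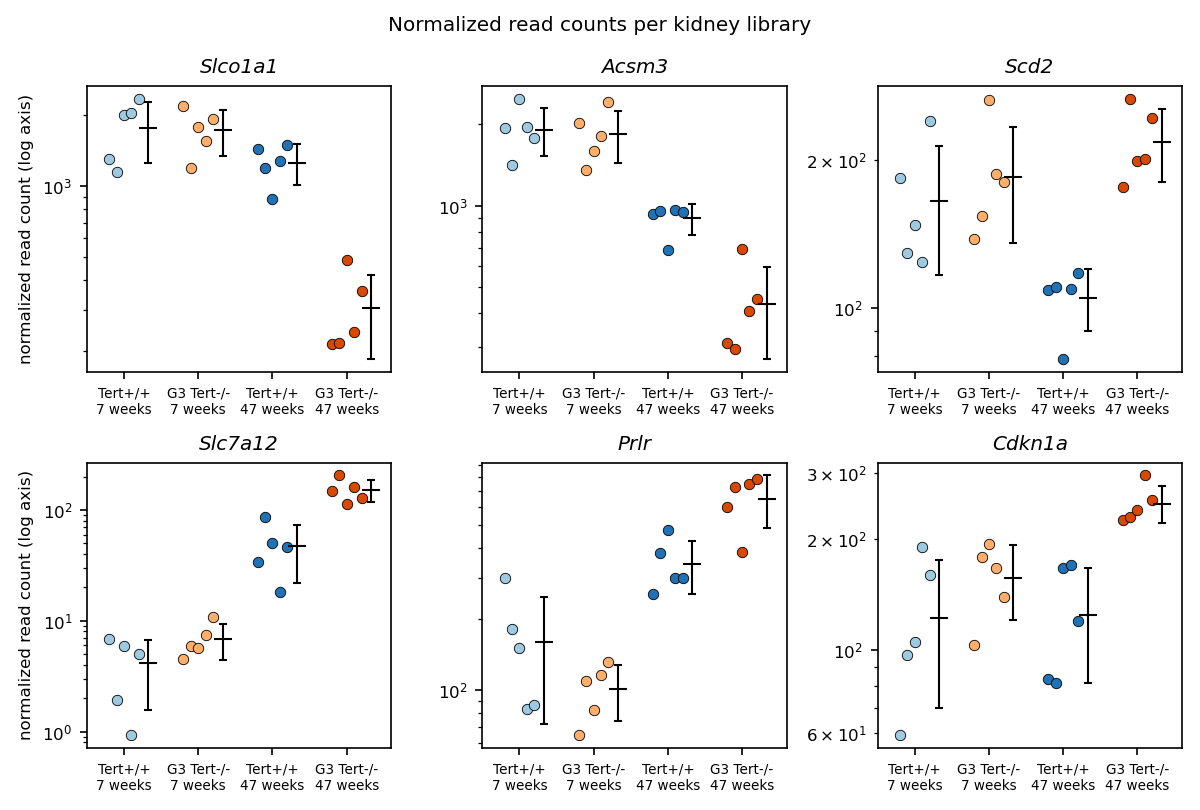
Normalized read counts on log axes, 1 point per library, with mean and SD bars per group, for Slco1a1, Acsm3, Scd2, Slc7a12, Prlr and Cdkn1a. Slco1a1 averaged 304 in old G3 Tert-/- kidneys and between 1256 and 1764 in the other groups, while Slc7a12 averaged 47.3 and 152 at 47 weeks and 4.13 and 6.85 at 7 weeks.

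Of the other 11 calls at 47 weeks, 10 were lower in G3 Tert-/- kidneys. Nudt19, a peroxisomal coenzyme A hydrolase, fell 1.68-fold (log2 fold change -0.75, adjusted p = 0.0125). Hsd17b11, a steroid dehydrogenase of lipid droplets, fell 1.60-fold, Acsm2, an acyl-CoA synthetase, fell by 0.59 on the log2 scale and Papss1, which makes the sulfate donor of the cell, fell 1.44-fold (adjusted p = 0.0381, 0.0238 and 0.0386). Lipo3, a member of the lipase family, fell from 167 ± 20.9 to 81.7 ± 17.3 (log2 fold change -1.04, adjusted p = 0.00265). Sec14l3, a lipid-binding protein, fell by 1.30 and the protease inhibitor Pzp by 0.95 on the log2 scale (adjusted p = 0.0125 and 0.0238). The 4 called genes outside the naming rule, given after their values were seen, were Cntnap5a (-2.50), Gm48281 (-1.50), Gm6300 (-2.64) and the Y-chromosome gene Gm47283 (3.01), as log2 fold changes.

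p53 targets were higher as a list in old G3 Tert-/- kidneys. 17 of 22 members had a positive log2 fold change, with a median of 0.20 (adjusted p = 0.00344, and adjusted p = 0.0193 with an estimated correlation). No member passed over all genes, and 1 rose when adjusted over the list alone. That gene was Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727). It was 124 ± 42.8 in old Tert+/+ and 249 ± 28.8 in old G3 Tert-/- kidneys (log2 fold change 1.06, SE 0.26, adjusted p = 0.167, and 0.00952 adjusted over the list alone). Without both libraries that stood apart, Cdkn1a passed over all genes (adjusted p = 0.0209). The senescence list did not pass (adjusted p = 0.458), and its members Cdkn1a and Glb1, the lysosomal beta-galactosidase (log2 fold change -0.40, adjusted p = 0.142), lay on opposite sides of 0.

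No panel gene of fibrosis or epithelial-to-mesenchymal transition passed at 47 weeks. Log2 fold changes were 0.60 (SE 0.47) for the transition factor Snai1, 0.25 (SE 0.17) for the intermediate filament Vim, 0.30 (SE 0.21) for smooth muscle actin Acta2 and 0.02 (SE 0.14) for E-cadherin Cdh1. They were -0.20 (SE 0.18) for Col1a1, 0.13 (SE 0.24) for Col3a1, 0.10 (SE 0.16) for fibronectin Fn1, -0.21 for Snai2, -0.07 for Zeb1, -0.23 for Tgfb1, 0.08 for Kl and 0.09 for Umod. Adjusted p-values of these 12 genes ran from 0.853 to 0.988. Twist1 and the tubular injury genes Havcr1 and Lcn2 lay below the filter, with group means at 47 weeks of 3.39 and 4.93, 8.95 and 1.63, and 6.13 and 8.65 (Tert+/+ first). The extracellular matrix list (median 0.11, adjusted p = 0.510) did not pass. Neither did the mesenchymal list, whose median was -0.01 and whose mean (0.06) and test pointed up (adjusted p = 0.567), nor the TGF-beta signalling list (median 0.06, adjusted p = 0.521).

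9 further lists passed at 47 weeks with the preset correlation and not with an estimated one. The interferon response list was higher, with 29 of 34 members positive and a median of 0.25 (adjusted p = 1.67e-05, but adjusted p = 0.234 with an estimated correlation), and no member rose over all genes. 2 members rose when adjusted over the list alone, Ifit1 (0.93) and Oasl2 (0.64), both named after their values were seen. The B cell and plasma cell list was lower, with all 9 members negative and a median of -1.30 (adjusted p = 0.000755, but adjusted p = 0.390 with an estimated correlation). Erythroid (median 0.49) and collecting duct (0.14) lists were higher (adjusted p = 0.00133 and 0.0113), each with adjusted p = 0.284 with an estimated correlation, and 1 erythroid gene, Alas2, rose when adjusted over the list alone. The collecting duct score of Tert+/+ young replicate 1 was 0.50, against -0.26 to -0.04 in its group. Urothelium (median 0.74), macrophage (0.18) and cholesterol biosynthesis (0.19) lists were higher, each with adjusted p = 0.0366. Their values were adjusted p = 0.655, 0.655 and 0.390 with an estimated correlation, and the cholesterol score of Tert+/+ old replicate 4 was 0.19 against -0.24 to -0.14 in its group. Fatty acid oxidation (median -0.09, adjusted p = 0.0376) was lower, with adjusted p = 0.390 with an estimated correlation. The hepatocyte list was lower (median -0.41, adjusted p = 0.0169, but adjusted p = 0.428 with an estimated correlation), and its score was 2.26 in Tert+/+ old replicate 4 against -0.18 to 0.15 in the rest of that group.

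The remaining 24 lists did not pass at 47 weeks, with adjusted p from 0.0652 to 0.734. These were extracellular matrix, mesenchymal, epithelial junction, TGF-beta, senescence, telomere maintenance, antigen presentation, T cell, complement, tubular injury, proximal tubule, thick ascending limb, distal tubule, podocyte, endothelial, fibroblast, cell cycle, postnatal growth, oxidative phosphorylation, circadian clock, immediate early, mitochondrial-encoded, ribosomal protein and adipocyte. Of the untestable lists, neutrophil genes had 4 tested members with a median of 0.90, of which 2 rose when adjusted over the list alone and none over all genes. Adrenal cortex had 2 tested members (median 0.25), pancreatic acinar 1 (-0.24) and skeletal muscle 0. In total 14 genes passed at 47 weeks, 2 higher and 12 lower, and 962 had an unadjusted p under 0.05, where chance gives 732. The edgeR test called 15 and DESeq2 52, of which 36.5% were higher against 14.3% here. Slco1a1 and Lipo3 were the 2 of 10 named calls that passed whichever library was left out, and without G3 Tert-/- old replicate 2 or replicate 4 the count was 2.

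**Figure D2:**
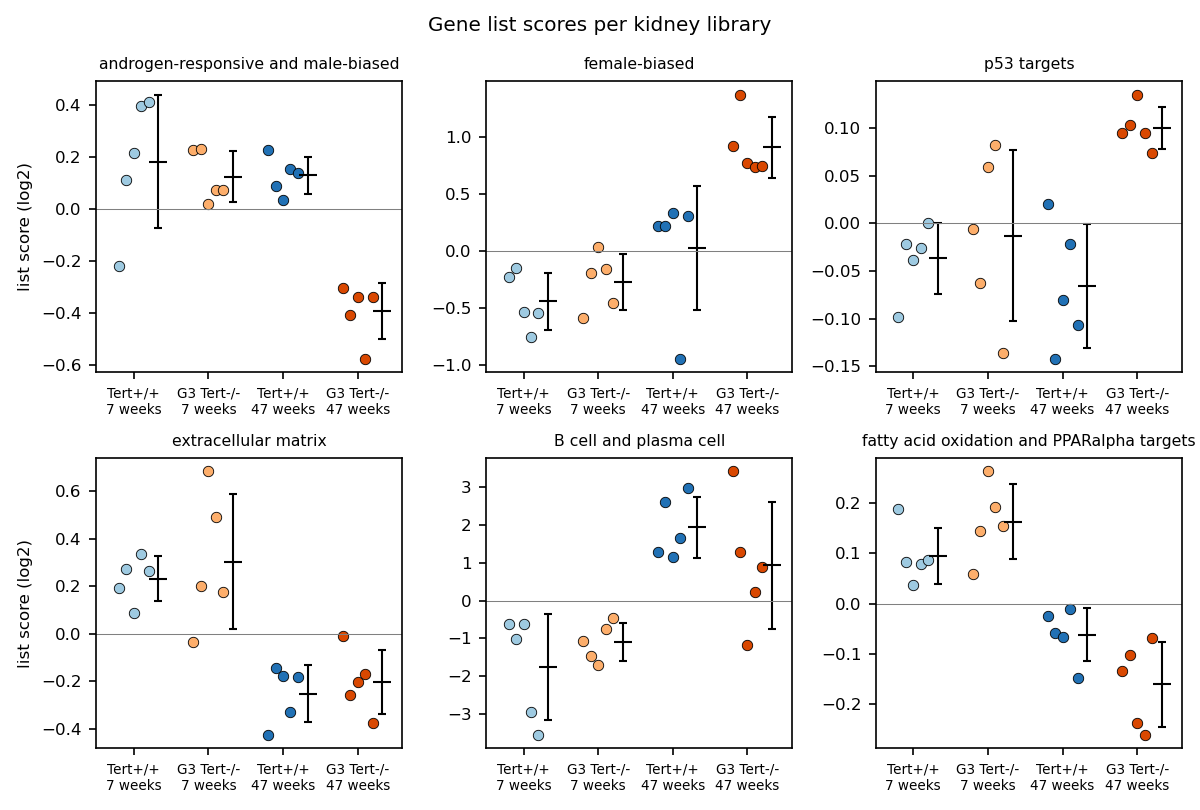
Scores of 6 gene lists (median over members of centred log2 values), 1 point per library, with mean and SD bars per group. Male-biased scores were -0.58 to -0.30 in old G3 Tert-/- kidneys and 0.04 to 0.23 in old Tert+/+ kidneys, and extracellular matrix scores averaged 0.23 and 0.30 at 7 weeks and -0.25 and -0.20 at 47 weeks (Tert+/+ first).

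The genotype comparison at 7 weeks asks the same question in young mice. No gene passed with limma, where 1559 genes had an unadjusted p under 0.05 (732 are expected by chance) and the smallest adjusted p was 0.0969. The edgeR test also called 0, and DESeq2 called 13. The 5 genes with the smallest p included the mitochondrial transfer RNAs mt-Tn, at 803 ± 332 in Tert+/+ and 239 ± 98.3 in G3 Tert-/- kidneys, and mt-Te, at 278 ± 219 and 67.8 ± 38.2. F2rl1, a protease-activated receptor (chromosome 13, 95511732 to 95525227), was 68.9 ± 25.7 and 27.0 ± 8.63 (log2 fold change -1.32, SE 0.27, adjusted p = 0.335). Arpp21, a cAMP-regulated phosphoprotein, was 36.7 ± 25.3 and 9.05 ± 4.01, and the zinc finger gene Zfp512 was 106 ± 19.7 and 157 ± 15.8 (adjusted p = 0.241 and 0.351). Tert+/+ young replicate 1 held 662 counts of mt-Te, against 145 to 254 in the rest of its group, and 81.7 of Arpp21, against 21.5 to 30.3. Without it, 936 genes had an unadjusted p under 0.05.

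In the young panel, Cdkn1a was 122 ± 52.3 in Tert+/+ and 156 ± 35.6 in G3 Tert-/- kidneys (log2 fold change 0.43, SE 0.26, adjusted p = 0.516). Log2 fold changes were 0.43 (SE 0.18) for Col1a1, 0.34 (SE 0.24) for Col3a1, 0.54 (SE 0.21) for Acta2, 0.65 (SE 0.47) for Snai1, -0.81 (SE 0.26) for Tgfb1 and -0.38 (SE 0.14) for Zeb1, with adjusted p from 0.435 to 0.589. The other panel genes tested, Fn1 (0.10), Vim (0.21), Cdh1 (0.17), Snai2 (0.22), Kl (0.32) and Umod (-0.28), had adjusted p from 0.483 to 0.818. Tgfb1 was 115 in Tert+/+ young replicate 1, against 34.5 to 51.1 in the other 4. The cell cycle list (median 0.24, 24 of 28 members positive) and the oxidative phosphorylation list (median 0.11, 34 of 51 positive) were higher in young G3 Tert-/- kidneys with the preset correlation, each at adjusted p = 0.0146. Both had adjusted p = 0.937 with an estimated correlation, and 0 members of either rose over all genes or adjusted over the list alone. In the telomere maintenance list, which did not pass (adjusted p = 0.968), Tert was lower and Acd higher when adjusted over the list alone. The male-biased list had a median of -0.04 at this age (adjusted p = 0.673), the female-biased list 0.40 (adjusted p = 0.391) and the p53 list 0.01 (adjusted p = 0.909). Removing Tert+/+ young replicate 2 gave 2 calls over all genes, and no other single library gave any.

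The age comparison in Tert+/+ mice describes kidneys with telomerase at 47 against 7 weeks. Old kidneys held more immunoglobulin transcripts and fewer transcripts of collagens and other matrix proteins. The light chain gene Igkc rose from 122 ± 95.8 to 3132 ± 1865 (n = 5 each, log2 fold change 4.94, SE 0.70, adjusted p = 0.000417), Igha from 152 ± 133 to 1813 ± 548 and Jchain, which links IgA and IgM, from 12.9 ± 9.02 to 201 ± 99.2. Pigr, the epithelial receptor that carries these antibodies into the lumen, rose 4.15-fold (log2 fold change 2.05, SE 0.21, adjusted p = 1.18e-05). Col3a1 (chromosome 1, 45311538 to 45349706) fell 2.79-fold, from 367 ± 55.2 to 136 ± 45.2, and Col1a1 (chromosome 11, 94936224 to 94953042) fell 2.24-fold, from 376 ± 46.4 to 168 ± 33.8 (adjusted p = 0.00189 and 0.00137).

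The B cell and plasma cell list had all 9 members higher in old Tert+/+ kidneys, with a median of 4.09, and 5 rose over all genes (8 adjusted over the list alone). Ighg2c was among them, at 2.55 ± 4.24 in young and 357 ± 421 in old kidneys, and no fold is given because the young group is near the limit of 3 reads. All 11 antigen presentation genes were higher (median 0.64), and 2 rose over all genes (8 adjusted over the list alone), the class II gene H2-Ab1 (log2 fold change 0.75) and H2-DMb1 (0.64). Complement C4b rose 3.54-fold. In the extracellular matrix list, 27 of 34 members were lower (median -0.47), and 8 fell over all genes (16 adjusted over the list alone). Besides the collagens already named, Sparc fell by 0.90, Col4a1 by 0.69, Col5a2 by 1.04 and Fn1 by 0.99 on the log2 scale. 24 of 29 fatty acid oxidation genes were lower (median -0.15), and 2 fell over all genes (5 adjusted over the list alone). They were Ehhadh, a peroxisomal enzyme (-0.88), and Cyp4a14, an omega-hydroxylase that the female-biased list also holds (-2.25). 19 of 20 cholesterol biosynthesis genes were lower (median -0.34), and 4 fell when adjusted over the list alone. These 5 lists passed with the preset correlation (adjusted p from 8.67e-16 to 5.45e-05) and each had adjusted p = 0.0363 with an estimated correlation. Without both libraries that stood apart, antigen presentation and fatty acid oxidation had adjusted p = 0.0679 and 0.124 with an estimated correlation.

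14 other lists passed in old Tert+/+ kidneys with the preset correlation and not with an estimated one. The fry test passed 7 lists in this comparison. Interferon response (median -0.21), fibroblast (-0.21), podocyte (-0.14), proximal tubule (-0.15), cell cycle (-0.19) and oxidative phosphorylation (-0.08) lists were lower. They had adjusted p = 0.162, 0.233, 0.218, 0.310, 0.310 and 0.382 with an estimated correlation. T cell (0.69), macrophage (0.28), complement (0.14), tubular injury (0.17), female-biased (0.83), urothelium (1.23), ribosomal protein (0.17) and hepatocyte (0.62) lists were higher. Of the members of these lists, 2 fibroblast genes, Top2a and Cyp4a14 fell over all genes, and Slc7a12, Prlr and C4b rose. The values of the higher lists were adjusted p = 0.217, 0.351, 0.264, 0.233, 0.234, 0.335, 0.310 and 0.353 with an estimated correlation. The ribosomal protein genes spread more in the 2 libraries that stood apart (SD 0.869 and 0.642) than in any other (at most 0.343).

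Individual changes in old Tert+/+ kidneys included the sex-biased transporters and enzymes. Slc7a12 (chromosome 3, 14480697 to 14505830) rose from 4.13 ± 2.58 to 47.3 ± 25.5 (log2 fold change 3.25, SE 0.38, adjusted p = 3.26e-05), Prlr rose 2.33-fold and Cyp4a12a 3.48-fold, while Acsm3 fell 2.12-fold. The male-biased list did not pass with age (7 members positive and 5 negative, median 0.00, mean 0.01, test pointing down, adjusted p = 0.610). Azgp1, a secreted lipid-mobilizing glycoprotein, rose 4.96-fold. Slc12a3, the thiazide-sensitive cotransporter of the distal convoluted tubule, rose 1.49-fold, the only called member of its list. The transcription factor Neurog2 was 0.193 ± 0.431 in young and 21.4 ± 7.84 in old kidneys. Akr1c18, a progesterone-inactivating enzyme, fell from 174 ± 138 to 6.497 ± 3.57, and Ctxn3 was 22.8 ± 17.6 and 1.24 ± 1.33. Hist1h4h, a histone gene, fell 4.12-fold, Mogat2, an acyltransferase, 2.79-fold, the deiodinase Dio1 2.52-fold, lipoprotein lipase Lpl 2.14-fold and the cell cycle gene Top2a 1.99-fold. In total 95 genes passed, 59 higher and 36 lower (62.1% higher), but 46.0% of the DESeq2 calls were higher, so the balance of directions depends on the method. The calls of H2-DMb1, Cyp4a12a, Cyp4a14 and Top2a ended without both libraries that stood apart (adjusted p = 0.0846, 0.169, 0.0765 and 0.0737). Their log2 fold changes in that fit were 0.537, 1.205, -1.991 and -0.962, against 0.641, 1.799, -2.247 and -0.995 with all libraries. The calls of Prlr and Ehhadh ended without at least 1 library.

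The age comparison in G3 Tert-/- mice describes the same interval without telomerase. Matrix, fatty acid oxidation and male-biased transcripts were lower in old kidneys and female-biased transcripts higher. Col1a1 fell 3.48-fold, from 532 ± 203 to 144 ± 14.5 (log2 fold change -1.80, SE 0.18, adjusted p = 2.07e-06). Slco1a1 fell 5.85-fold, from 1723 ± 378 to 304 ± 118 (log2 fold change -2.55, SE 0.23, adjusted p = 3.54e-07). Slc7a12 rose 19.7-fold, from 6.85 ± 2.40 to 152 ± 34.8, and Prlr 6.37-fold, from 101 ± 27.0 to 649 ± 164 (adjusted p = 3.54e-07 and 2.89e-06). In total 327 genes passed, 136 higher and 191 lower.

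In the extracellular matrix list, 26 of 34 members were lower (median -0.45, adjusted p = 0.0369 with an estimated correlation), and 10 fell over all genes. Adjusted over the list alone, 17 fell and 2 rose. Col3a1 fell 3.23-fold, Sparc 2.23-fold, Col4a2 1.80-fold and Fn1 from 130.0 ± 33.1 to 62.9 ± 8.26. 26 of 29 fatty acid oxidation genes were lower (median -0.32, adjusted p = 0.00885 with an estimated correlation), and 7 fell (11 adjusted over the list alone), among them Cpt2 (-0.52), Eci2 (-0.57) and Acadl (-0.47), as log2 fold changes. 9 of 12 male-biased genes were lower (median -0.43, adjusted p = 0.0173 with an estimated correlation), and 4 fell over all genes and adjusted over the list alone. They were Slco1a1, Acsm3 (4.39-fold), Odc1 (2.08-fold) and Gusb (1.75-fold). 5 of 6 female-biased genes were higher (median 1.14, adjusted p = 0.0369 with an estimated correlation), and 2 rose over all genes, Slc7a12 and Prlr. Adjusted over the list alone 4 rose and 1 fell. Without both libraries that stood apart, neither of which is a G3 Tert-/- library, the matrix list had adjusted p = 0.0691 with an estimated correlation. The log2 fold changes of Col1a1 (-1.80), Sparc (-1.16) and Col3a1 (-1.69) were the same in that fit, since it dropped no library compared here.

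12 more lists passed in old G3 Tert-/- kidneys with the preset correlation and not with an estimated one. The fry test passed 13 lists in this comparison. Cell cycle genes were lower (23 of 28, median -0.46), and 5 fell over all genes (12 adjusted over the list alone), among them Top2a (2.14-fold), Cenpf (2.31-fold), Tpx2 (2.56-fold) and Nusap1 (2.01-fold), with adjusted p = 0.0531 with an estimated correlation. 49 of 51 oxidative phosphorylation genes were lower (median -0.28) and 4 fell (9 adjusted over the list alone), namely Uqcrb, Uqcrc2, Cycs and Cox6a1 (1.35-fold to 1.38-fold), with adjusted p = 0.0617 with an estimated correlation. 19 of 27 proximal tubule genes were lower (median -0.29) and 5 fell, among them the glucose transporter Slc5a2 (1.49-fold), the amino acid transporter Slc6a19 (1.96-fold), Keg1 (1.75-fold) and Acsm1 (1.49-fold), with adjusted p = 0.0697 with an estimated correlation. Adjusted over the list alone, 8 proximal tubule genes fell and 1 rose. All 11 antigen presentation genes were higher (median 0.70), and 2 rose (7 adjusted over the list alone), H2-Ab1 (1.99-fold) and H2-DMb1 (1.63-fold), with adjusted p = 0.0617 with an estimated correlation. B cell (median 1.64), T cell (0.71), macrophage (0.43) and fibroblast (-0.27) lists each had adjusted p = 0.167 with an estimated correlation. Ighg2c was the 1 B cell gene that rose over all genes, and 1514 of its counts were in G3 Tert-/- old replicate 1, against at most 102 in the rest of that group. Urothelium (1.86), thick ascending limb (0.34), tubular injury (0.16) and immediate early (0.27) lists had adjusted p = 0.275, 0.394, 0.232 and 0.244 with an estimated correlation.

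Among single genes in old G3 Tert-/- kidneys, Cyp2d12, a cytochrome P450, rose 9.93-fold (log2 fold change 3.31, SE 0.22, adjusted p = 2.82e-09), from 106 ± 26.6 to 1030 ± 26.7. The adhesion molecule Ceacam2 rose 7.38-fold, the water channel Aqp4 7.31-fold, Pigr 6.61-fold, Azgp1 6.21-fold, the neutrophil protein S100a9 4.66-fold, C4b 2.68-fold, the plasma protein Apoh 2.42-fold and Slc12a3 1.54-fold. Akr1c18 fell from 167 ± 40.5 to 2.48 ± 2.59 (adjusted p = 5.14e-07). The organic anion transporter Slc22a7 fell 5.33-fold, Angptl7 5.13-fold, Col6a6 4.41-fold, Hist1h4h 4.14-fold, the sterol enzyme Cyp51 1.75-fold, the calcium-binding protein Calb1 1.52-fold and Glb1 1.47-fold. Of the 47 named calls, 33 passed whichever library was left out. Those lost without at least 1 library included S100a9, Slc6a19, Slc5a2, Calb1, Cenpf, Tpx2, Nusap1, the 4 oxidative phosphorylation genes, Eci2 and Acadl.

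**Figure D3:**
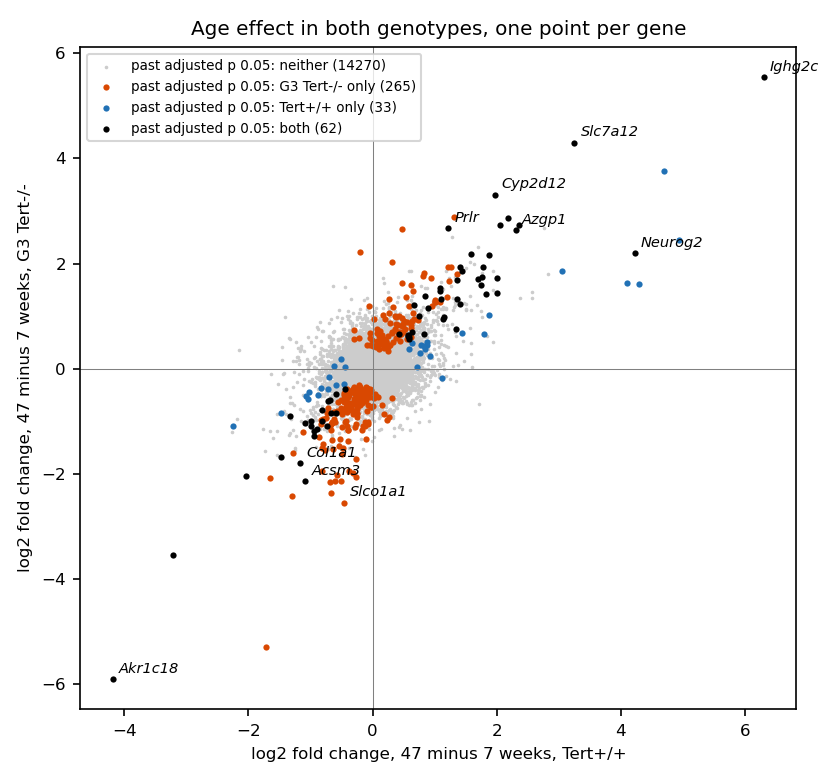
Log2 fold change with age in Tert+/+ (horizontal axis) and G3 Tert-/- kidneys (vertical axis), 1 point per gene, coloured by the comparisons in which the gene passed. 62 genes passed in both, all with the same sign, 33 in Tert+/+ alone and 265 in G3 Tert-/- alone.

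The age comparisons called overlapping genes in the 2 genotypes, and they share no library. The labels give no processing date, so age cannot be told apart from a processing step that differed between old and young groups. 40 genes rose in both, where independent lists would share 0.55, and 22 fell in both, where they would share 0.47, with 0 called in opposite directions. Of the 95 genes called in Tert+/+ kidneys, 91 had the same sign in G3 Tert-/- kidneys. Across all tested genes the age effects correlated at r = 0.447 (rho = 0.275). That 327 genes passed in G3 Tert-/- and 95 in Tert+/+ does not by itself show a difference, which the interaction tests.

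The interaction asks whether the genotype effect differs between ages, or equally whether age acts differently in the 2 genotypes. Slco1a1 was the 1 gene that passed (interaction log2 fold change -2.09, SE 0.32, adjusted p = 0.0199): its genotype difference was -2.10 at 47 weeks and -0.01 at 7 weeks. All 12 male-biased genes had a negative interaction, with a median of -0.46 (adjusted p = 1.14e-06, and adjusted p = 0.0194 with an estimated correlation), 1 fell over all genes and 4 adjusted over the list alone. The male-biased list had adjusted p = 0.133 with an estimated correlation without both libraries that stood apart, and Slco1a1 had adjusted p = 0.0640 with an interaction log2 fold change of -1.98. Slco1a1 also lost its call in 10 of the 20 fits that left out 1 library, with a highest adjusted p of 0.0733, while its log2 fold change stayed between -2.28 and -1.95.

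7 other lists passed the interaction test with the preset correlation and not with an estimated one. The interferon response list was relatively higher in old G3 Tert-/- kidneys, with 30 of 34 members positive and a median of 0.38, and the female-biased list with a median of 0.85. Each had adjusted p = 0.265 with an estimated correlation. Cholesterol biosynthesis (0.26) was higher too, with adjusted p = 0.468 with an estimated correlation. B cell (-1.03), cell cycle (-0.23), oxidative phosphorylation (-0.18) and ribosomal protein (-0.14) lists were relatively lower. They had adjusted p = 0.648, 0.516, 0.498 and 0.916 with an estimated correlation. The extracellular matrix list had a median of -0.04 (adjusted p = 0.785), and the p53 list 0.11 (adjusted p = 0.0972).

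Genotype effects at 47 and 7 weeks, measured in separate mice, correlated weakly across the 14630 genes (r = 0.241, rho = 0.198). Of the 14 genes called at 47 weeks, 10 had the same sign at 7 weeks. The correlation was 0.032 without Tert+/+ old replicate 4 and 0.063 without both libraries that stood apart.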

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

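Most tests below were chosen after the result they weigh had been seen, including every count over 100 splits of the libraries. Those on a GC trend, a different mix of cells and a chromosome segment were written before they were run. The rule for single values marks about 1 group in 20 by chance. It marked 42 values in 516 groups of 5 (8.1%), 8 of them in Tert+/+ young replicate 1 and 7 in Tert+/+ old replicate 4.

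Sex-biased genes shifted in old G3 Tert-/- kidneys, with male-biased genes lower (median -0.48) and female-biased genes higher (median 1.14). Fewer proximal tubule cells would lower the other proximal tubule genes too, but their median was -0.08 (bootstrap SE 0.064, 27 genes). That SE comes from resampling genes and does not measure the spread between mice. A loss limited to part of the proximal tubule was not tested. The libraries that stood apart are not the cause, because the male-biased list had adjusted p = 0.00117 with an estimated correlation without them. Lower androgen action was not tested: 10 of 10 old G3 Tert-/- scores lay beyond every old Tert+/+ library, which restates the shift and would follow from any cause. Hormone levels and testis weight would bear on it, though not on androgen action within the kidney alone, and are not given in the sources used here.

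With genotype compared over both ages pooled, 15 of 205 tested genes within 20 Mb of Tert had an unadjusted p under 0.01 (7.32%), against 373 of 14345 elsewhere (2.60%, Fisher's exact p = 0.000404). The window was chosen after the excess was seen, neighbouring genes are not independent and a random split gave 14 such genes, so this p and that within 40 Mb overstate the excess. Within 40 Mb it was 25 of 412 against 363 of 14138 (p = 0.00013, r = 0.369). A chromosome segment inherited with the targeted allele predicts effects shared by both ages, and the correlation in the 20 Mb window was 0.421, against a median of 0.242, a 95th percentile of 0.386 and a highest value of 0.543 in 208 other blocks. Effects within this window may therefore come from such a segment rather than short telomeres. The blocks overlapped each other. Across all genes the correlation fell from 0.241 to 0.063 without both libraries that stood apart, and the window was not tested again without them. The value of r within 40 Mb was below the 95th percentile of the blocks. Those blocks held 205 genes each and the 40 Mb window 412, so this comparison decides nothing. Of the 4 genes that passed with ages pooled, F2rl1 lay on chromosome 13 (adjusted p = 0.0186). It starts at 95511732, just outside the 20 Mb window and inside the 40 Mb one, so its difference may come from such a segment too. Among the 15 genes, some of which were higher, were the steroid reductase gene Srd5a1 and the regulator of sex-limitation gene Rsl1, chosen after their values were seen. Srd5a1 was lower by 0.73 at 47 weeks and 0.61 at 7 weeks on the log2 scale, and Rsl1 by 1.03 and 0.99. Neither passed with ages pooled (adjusted p = 0.302 and 0.368). Whether these genes or such a segment affect genes elsewhere, the sex-biased genes included, was not tested.

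Tert+/+ young replicate 1 and Tert+/+ old replicate 4 departed together from the other 18 libraries. Depth does not explain it, since 0 of the 2 totals lay outside the range of the others, and nor does a GC trend near the 3′ end, after whose removal the SDs of abundant genes were 0.585 and 0.450 against at most 0.358 elsewhere. A different mix of cells alone would leave ribosomal protein genes together, but their SDs were 0.869 and 0.642, against at most 0.343. This cannot exclude a different mix in addition. Tert+/+ old replicate 4 held more of most listed hepatocyte transcripts than any other library (Alb 462 against at most 89.8). A shared step of RNA handling or library making remains undecided. This pair is 1 of 150 pairs of libraries from different groups. Its departures correlated at 0.448, against a median of 0.011 and a highest value of 0.556 in the other pairs. RNA quality per library would decide.

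The libraries were also split at random 100 times, with the real grouping counted. As many genes as the real 14 at 47 weeks came in 1 split (highest other 4). All 100 reached the 0 at 7 weeks, as any count must, so this decides nothing (highest other 2). As many as the 95 with age in Tert+/+ came in 1 split (highest other 71). The 327 with age in G3 Tert-/- were matched in 1 (22), and the 1 interaction gene in 3 (1). For gene lists the counts were 12 splits at 47 weeks (real 12, highest other 15), 84 at 7 weeks (2 and 14), 1 with age in Tert+/+ (19 and 16), 12 with age in G3 Tert-/- (16 and 24) and 32 for the interaction (8 and 15). Counts of lists with the preset correlation are therefore matched by random groups in 4 of the 5 comparisons. Medians at 47 weeks as far from 0 came in 1 split for male-biased (real -0.481, highest other 0.398), 1 for female-biased (1.143 and -0.902), 1 for p53 (0.205 and 0.178) and 4 for interferon (0.248 and -0.296). A correlation of genotype effects as far from 0 as 0.241 came in 16 splits (highest other -0.384), one of age effects as far as 0.447 in 1 (0.376), and 15 genes near Tert in 1 (14).

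In Tert+/+ young replicate 1, Tgfb1 was 115 (34.5 to 51.1 in the rest of its group), Arpp21 81.7 (21.5 to 30.3), mt-Te 662 (145 to 254), Mogat2 143 (69.4 to 76.3) and Ehhadh 542 (264 to 309). Its SD of abundant genes was 0.595, its collecting duct score 0.499 and its mitochondrial-encoded score -0.439. In Tert+/+ old replicate 4, mt-Te was 151 (59.0 to 81.9), Col6a6 27.0 (7.25 to 11.1), the number of genes above 0 was 18628 (19001 to 19137) and the SD of abundant genes 0.470. Its scores were 2.262 for hepatocyte, -0.941 for female-biased and 0.186 for cholesterol biosynthesis genes.

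G3 Tert-/- old replicate 1 held 7029 counts of Igkc (183 to 1218 in the rest of its group), 1514 of Ighg2c (1.04 to 102), 463 of Jchain (9.35 to 125) and 38.0 of Cenpf (17.4 to 22.9). In Tert+/+ old replicate 3, Scd2 was 78.9, Acsm3 686 and Cyp4a14 183, and in Tert+/+ old replicate 2 Gusb was 146. In Tert+/+ young replicate 5, Slc12a3 was 4449, Slc22a7 219.6 and Calb1 3283, and Neurog2 was 0.9645 in Tert+/+ young replicate 2, which is 1 read. In G3 Tert-/- young replicate 3, Col3a1 was 929 (276 to 454), Gusb 167, Cpt2 651 and the complement score 0.359. In G3 Tert-/- young replicate 5, Arpp21 was 16.1 and Odc1 3464, in replicate 2 Keg1 was 11775 and Ighg2c 0.979, in replicate 1 Slc6a19 was 1172, and in replicate 4 the telomere maintenance score was 0.285. In G3 Tert-/- old replicate 5, Tgfb1 was 57.6 and Mogat2 34.4 (34.35), in replicate 4 Umod was 14304, in replicate 3 H2-Ab1 was 701, and in replicate 2 the female-biased score was 1.367.

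The interaction of Slco1a1 was -2.09. Median interactions were -0.462 for male-biased, 0.847 for female-biased, 0.382 for interferon, -1.026 for B cell, -0.227 for cell cycle, -0.176 for oxidative phosphorylation, 0.262 for cholesterol and -0.142 for ribosomal protein genes, of which only the male-biased list passed with an estimated correlation.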

How the results depend on the processing

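Calls at the margin moved with the method, and no named call changed sign when a library was left out. The 14 calls at 47 weeks became 52 with DESeq2 (all 14 shared), 95 with array quality weights (14 shared, 40% higher), 15 with edgeR (13 shared), 6 in a model of only the 10 libraries compared (6 shared) and 2 to 19 when 1 library was left out. The low counts came without Tert+/+ old replicate 1 (4) or 5 (7), or G3 Tert-/- old replicate 1 (8), 2 (2) or 4 (2). The 0 calls at 7 weeks became 13 with DESeq2, 1 with weights and 0 to 2 with 1 library left out, with 2 without Tert+/+ young replicate 2. The 95 age calls in Tert+/+ became 211 with DESeq2 (94 shared, 97 higher and 114 lower), 367 with weights (95 shared, 187 higher and 180 lower), 53 with only the 10 libraries (51 shared) and 56 to 124 with 1 library left out. They were 60 without Tert+/+ young replicate 4, and 59, 56 and 56 without Tert+/+ old replicate 1, 2 or 5. The 327 in G3 Tert-/- became 530 with DESeq2 (327 shared), 1007 with weights (326 shared) and 192 to 501 with 1 library left out. They were 215 and 195 without G3 Tert-/- young replicate 1 or 2, 214, 195 and 192 without G3 Tert-/- old replicate 2, 4 or 5, and 501 without Tert+/+ young replicate 1. The 1 interaction call became 7 with DESeq2, 2 with weights, 0 with a robust prior and 0 to 2 with 1 library left out. It was 0 without Tert+/+ young replicate 2, G3 Tert-/- young replicate 1, 3 or 5, Tert+/+ old replicate 1, 2 or 5, or G3 Tert-/- old replicate 1, 2 or 4, and 2 without G3 Tert-/- old replicate 5. The cause was not tested for any of these libraries. The fit without both libraries that stood apart, added after the data were seen, gave 15, 0, 130, 664 and 0 calls in the 5 comparisons in the order used here. Array weights give these libraries little weight (0.21 and 0.30). Gene lists that passed went from 12, 2, 19, 16 and 8 to 3, 0, 5, 4 and 1 with an estimated correlation and to 3, 0, 7, 13 and 1 with fry. Of 120 named gene values, quantile normalization weakened 9 and TMM factors 1. The correlation of genotype effects was 0.032 to 0.296 with 1 library left out, 0.007 with weights, 0.159 without a filter and 0.309 with a filter of 50, all within its jackknife SE of 0.276. At 7161690 to 9757594 reads per library, genes near the filter are measured poorly. In simulation 31.3% of 1.5-fold changes were recovered, among changed genes with a mean of at least 20 only.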

Other observations

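Transcripts of cell types outside the main comparisons also varied. The neutrophil genes S100a8 and S100a9, chosen after their values were seen, were higher in old G3 Tert-/- than in old Tert+/+ kidneys by 1.58 (SE 0.58) and 1.66 (SE 0.49) on the log2 scale, with S100a9 at 57.3 ± 27.5 and 16.4 ± 5.83. Neither passed over all genes (adjusted p = 0.586 and 0.406). Tert+/+ old replicate 4 held 462 counts of Alb and 260 of Apoa1, both made mainly by hepatocytes, against at most 89.8 and 25.4 in the other libraries.

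With age in Tert+/+ mice, members of both sex-biased lists went both ways. Slc7a12 and Prlr rose by 3.25 and 1.22 and Acsm3 fell by 1.08 (log2 scale), but male-biased Cyp4a12a rose by 1.80 and female-biased Cyp4a14 fell by 2.25. Male-biased scores averaged 0.183 ± 0.258 in young and 0.130 ± 0.072 in old Tert+/+ kidneys, and female-biased scores -0.440 ± 0.250 and 0.027 ± 0.543. The female-biased list passed with the preset correlation (adjusted p = 0.0207) and with fry (0.0457), but had adjusted p = 0.234 with an estimated correlation. Old replicate 4 scored -0.941, while the other 4 old scores (0.216 to 0.329) lay above every young score (-0.756 to -0.149). Serum testosterone, and Slco1a1 in castrated, hormone-replaced G3 Tert-/- males, would test whether androgen action differs at 47 weeks. Genotyping of chromosome 13 would test whether the differences near Tert (correlation between ages 0.421) come from an inherited segment.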
